A study of Danio rerio with 2 samples.

How the data were processed

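Primary tumors of transgenic zebrafish were profiled by single-cell RNA sequencing, with 2 tumors of the MYCN line and 3 of the MYCN;LMO1 line. Per the labels, both lines are heterozygous on the AB background and the tissue is tumor in the adrenal gland. The labels' protocols name a Fluidigm C1 and SMART-seq workflow, while each deposited matrix holds at least 4095 barcodes, and the labels do not settle this. GEO holds 1 sample per genotype, with 2 and 3 matrices. The design text gives 2 and 3 tumors submitted individually, so each matrix was taken as 1 tumor, which is an inference. The sample titles place the genotypes in different parts of 1 dated library set, so genotype and library part coincide and cannot be separated.

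The deposited values are raw counts per barcode and gene, whole numbers of at least 0 with no normalization found in them, and Bowtie and GRCz11 are named without versions per the submitters' processing notes. The counting rule, the use of molecular tags and the barcode filter are not stated. The matrices held 28719 genes, including columns for human MYCN and EGFP but none for human LMO1, and 26805 barcodes (4224 and 4095 in the MYCN tumors, 5020, 7684 and 5782 in the MYCN;LMO1 tumors). Per the labels, 16630 cells were sequenced and 9082 were of high quality.

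Barcodes with at least 500 counts, at least 300 genes and at most 20% mitochondrial counts were kept (12971). Doublets were called within each tumor with scrublet (30 components), which called 27 barcodes, 0.208%. This is under 0.5% and too few to be a working doublet filter, so kept cells were not cleared of doublets, and removal of the top 5% of doublet scores was added as an alternative. The 12944 kept cells were scaled to 10000 counts, log-transformed and clustered together on 2000 variable genes, 30 principal components, 15 neighbors and Leiden resolution 1.0 (scanpy 1.11.5, leidenalg 0.10.2, scikit-learn 1.9.0, numpy 2.4.6, scipy 1.17.1, Python 3.11.15, seed 0), with no batch correction. Each of 30 clusters was named from 17 marker lists fixed before the data were examined. A class needed at least 3 markers of at least 50 CPM and log2 0.5 over the other cells, a mean over its top 6 markers of at least 0.8 and a lead of 0.5 over the next class (prior 20 CPM). The names are for likeness to marker genes, and 3 clusters stayed unnamed.

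The tumor was the replicate. Raw counts were summed per tumor and class, filtered by filterByExpr, scaled by TMM and tested with edgeR quasi-likelihood (edgeR 4.0.16, R 4.3.3) with Benjamini-Hochberg adjustment and a threshold of 0.05. A tumor entered a class with at least 20 cells. Class shares were tested with edgeR on cells per class with kept cells as library size, beside an exact permutation test. No paired analysis was possible because each genotype is 1 GEO sample and the tumors share no labelled numbers. Sums ranged from 335531 counts upward in macrophage-like cells, and the medians of kept counts per cell are in the report. On counts simulated from these tumors, 92% of 50 changes of 4 on the log2 scale were recovered in neuroblastoma-like cells and 95.8% of 48 over all cells. False calls numbered 8 of 10589 unchanged genes and 21 of 12505, and 5 of 4934 in macrophage-like cells. Over all cells the planted changes numbered 43 to 49 at each size, so 21 false calls were not few beside them. A list shifted by 1 was called in each class tested, and 0 of 16 unshifted lists were. Each simulated gene was drawn independently, so this does not show how often camera at its preset correlation calls unshifted lists of correlated genes. In the data the estimated correlation reached 0.975, for MHC class II presentation in neuroblastoma-like cells.

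Gene lists were tested with camera of limma 3.58.1 (preset correlation 0.01), beside an estimated correlation and fry, adjusted over lists within a class, with at least 3 measured members. At the preset correlation camera takes its degrees of freedom from the number of genes, so its p does not measure spread between tumors. With an estimated correlation they are limited by the number of tumors. The 17 lists were adrenergic core regulatory circuit, catecholamine synthesis and storage, neuronal maturation, mesenchymal neuroblastoma state, cell cycle, oxidative phosphorylation, glycolysis and hypoxia, dissociation stress, interferon response, MHC class II presentation, chemokines and receptors, complement and phagocytosis, proinflammatory cytokines, macrophage alternative activation, lipid handling and lysosome, extracellular matrix and integrins, and secreted proteases and matrix remodelling. Cycling cells were those with at least 2 counts over the cell cycle list after each cell was thinned to 500 counts without replacement.

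Genes to name were set by a rule fixed before the data were examined. It took lmo1 and mycn, then, among passing genes with non-overlapping CPM, a mean of at least 20 CPM and a symbol that is not a locus or clone name, the 10 largest changes in each direction (5 in other comparisons), and up to 4 members of each list by smallest p. Where fewer than 5 genes passed, it took the 10 with the smallest p as values. Gene values are CPM after TMM with SD over tumors, and the SE belongs to the log2 fold change. Intervals on shares are 95% Wilson intervals and cover counting error only.

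Alternatives set before the data were examined were RLE scaling, no low-count filter, DESeq2 1.42.0, a minimum of 1000 counts, a minimum of 300 counts and 200 genes for shares, doublets kept, Leiden resolutions 0.5 and 2.0, class-enriched genes only, TMM over classes, erythroid-like cells left out, other settings for cycling cells, and each tumor left out in turn. Those added after the results were seen were the top 5% of doublet scores removed, macrophage-like cells without the cluster whose neuroblastoma transcripts reached 15% of the neuroblastoma-like level, macrophage-like cells without clusters under 100 CPM for C1q genes and marco, neuroblastoma-like cells of 1000 to 3000 counts, cycling without thinning, and the alternatives for other classes. Figures were drawn with matplotlib 3.10.9.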

Results

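Single-cell transcriptomes were recorded from primary neuroblastomas of 2 transgenic zebrafish lines. Neuroblastoma is a tumor of the sympathoadrenal lineage, and in this model it is driven by human MYCN, a transcription factor amplified in aggressive human cases. The MYCN;LMO1 line also carries LMO1, a transcriptional co-regulator linked to neuroblastoma risk and metastasis. The design text lists 2 MYCN tumors and 3 MYCN;LMO1 tumors, submitted individually, and the 2 GEO samples hold 2 and 3 count matrices, so each matrix was read as 1 tumor. Total counts were 5117988 and 7613035 in the MYCN tumors, and 13272187, 24121493 and 8137829 in the MYCN;LMO1 tumors. After filtering, 1445 and 2375 cells remained from the MYCN tumors, and 2787, 5055 and 1282 from the MYCN;LMO1 tumors. The median count per kept cell was 1968 and 2083 in the MYCN tumors against 3713, 3973 and 3693 in the MYCN;LMO1 tumors, so depth differed along the genotypes. All fold changes below are log2 ratios of MYCN;LMO1 over MYCN, with the tumor as the replicate.

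The transgenes themselves were hardly seen. The column for human MYCN held 0 and 3 counts in the MYCN tumors and 3, 11 and 10 counts in the MYCN;LMO1 tumors, and endogenous mycn held at most 12 counts in any tumor. EGFP, the reporter column, held at most 8 counts in any tumor. Endogenous lmo1 in neuroblastoma-like cells measured 50.8 ± 33.9 CPM (SD, n = 2) in MYCN tumors and 30.8 ± 12.6 CPM (SD, n = 3) in MYCN;LMO1 tumors, with a log2 fold change of -0.71 (SE 0.49, edgeR adjusted p = 0.999). The matrices have no column for human LMO1, so the counts did not check which tumors carry it, and the genotype rests on the labels.

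The tumors held tumor cells, a large myeloid and lymphoid compartment, and small stromal classes. Of 12944 kept cells, 8772 were neuroblastoma-like, with the catecholamine enzyme dbh and the sympathoadrenal factors hand2 and phox2bb. There were 1539 macrophage-like cells (marco and the complement C1q genes), 1210 T/NK-like cells (cd8a, zap70 and the NK-lysin genes), 586 neutrophil-like cells (mpx and lyz) and 160 hematopoietic progenitor-like cells (myb). Erythroid-like (101), fibroblast-like (76), epithelial-like (72), hepatocyte-like (30), endothelial-like (21) and interrenal-like (18) cells were rarer. A further 359 cells in 3 clusters stayed unnamed.

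Neuroblastoma-like cells made up 38.1% and 65.5% of kept cells in the MYCN tumors and 74.8%, 72.5% and 71.3% in the MYCN;LMO1 tumors, means of 51.8% ± 19.4 (SD, n = 2) and 72.9% ± 1.78 (SD, n = 3). These shares leave out an unnamed cluster with markers of both neuroblastoma-like and erythroid-like cells. It held 8.44% of MYCN tumor 1 and 0.0842% to 2.65% of the other tumors. T/NK-like cells measured 12.6% ± 2.40 in MYCN and 7.33% ± 2.1 in MYCN;LMO1 tumors. Macrophage-like cells measured 12.7% ± 10.5 and 9.81% ± 2.43. Their share differed more between the MYCN tumors, 5.33% (95% Wilson interval 4.28% to 6.61%) and 20.1% (18.6% to 21.8%), than between the genotypes. Neutrophil-like cells made up 16.6% of MYCN tumor 1 and 1.22% of MYCN tumor 2, against 4.31% ± 2.16 in MYCN;LMO1 tumors. Erythroid-like cells (6.44%) and progenitor-like cells (6.30%) were also frequent in MYCN tumor 1, with 0% and 0.589% in MYCN tumor 2. Hepatocyte-like cells were counted in each MYCN;LMO1 tumor (7, 15 and 8 cells) and in neither MYCN tumor, where 0 cells allow shares of up to 0.208% and 0.126%.

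In the edgeR quasi-likelihood test of class sizes, 0 of 12 classes, the unnamed cells included, passed an adjusted p of 0.05. The log2 fold change was 0.49 for neuroblastoma-like cells (SE 0.72, edgeR adjusted p = 0.669), and the hepatocyte-like class had the smallest adjusted p, 0.115, the only class with an unadjusted p under 0.05. An exact two-sided permutation test of the shares gave p = 0.2 for neuroblastoma-like and T/NK-like cells and p = 0.8 for macrophage-like cells. With 10 splits of 5 tumors, p = 0.2 is the smallest that an exact permutation test can give. The intervals cover counting error only.

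**Figure D1:**
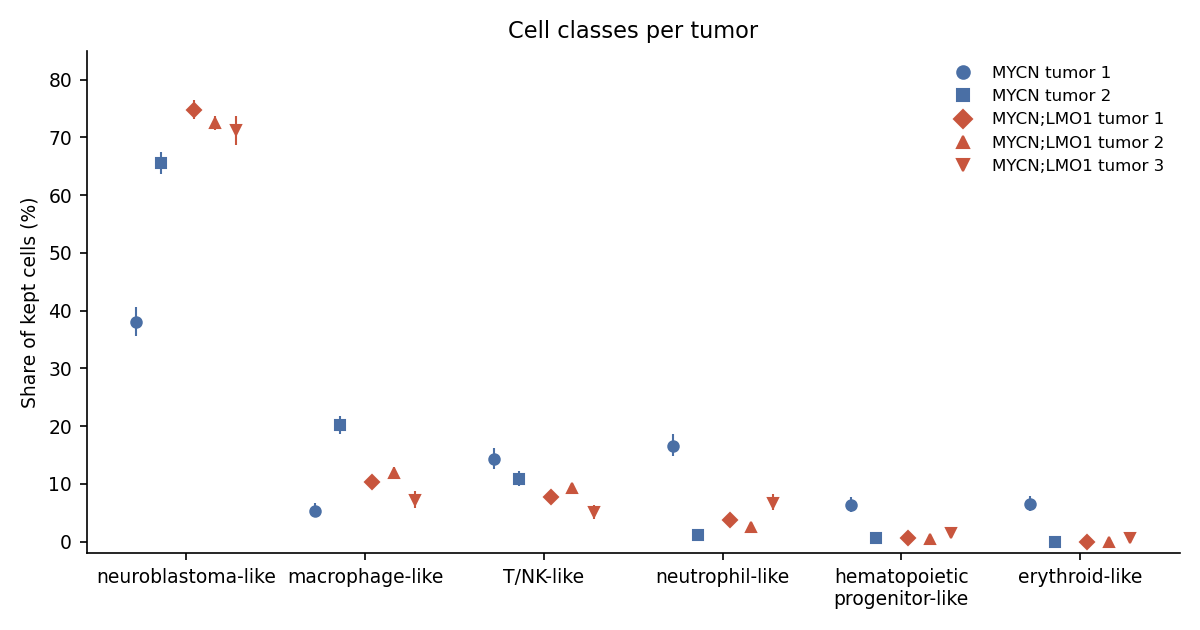
Share of kept cells (%, linear axis) in the 6 most frequent named classes, with 1 point per tumor (blue, MYCN; red, MYCN;LMO1) and 95% Wilson intervals as bars. The neuroblastoma-like shares of the MYCN;LMO1 tumors lie between 71.3% and 74.8%, and those of the MYCN tumors at 38.1% and 65.5%.

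Within neuroblastoma-like cells, the first question was whether the tumor cells themselves differed between the lines. The clearest difference was in si:ch211-261n11.7, an uncharacterised locus, which fell from 21.1 ± 9.75 CPM (SD, n = 2) in MYCN to 0.528 ± 0.109 CPM (SD, n = 3) in MYCN;LMO1 tumors. Its log2 fold change was -5.32 (SE 0.55, edgeR adjusted p = 0.0228), and it was the only gene of 12042 tested to pass. The 9 genes next by p are given as values. The ephrin receptor ephb4a measured 66.9 ± 58.4 CPM against 1.36 ± 0.277 (log2 fold change -5.61, adjusted p = 0.0571). The gene csad, whose enzyme acts in taurine synthesis, measured 9.47 ± 0.522 CPM against 0.541 ± 0.120, and the forkhead factor foxo1a 65.9 ± 41.5 against 12.5 ± 1.25. The SNARE gene vamp5 measured 50.7 ± 31.0 CPM against 9.88 ± 1.44. Values in MYCN;LMO1 tumors were the higher ones for kctd12.1, whose human counterpart encodes a GABA-B receptor subunit, at 7.36 ± 4.29 against 52.3 ± 16.8 CPM, and for the lipoxygenase gene alox5b.3, at 0.556 ± 0.327 against 9.64 ± 0.616 CPM. The remaining genes were si:ch73-329n5.1 (26.1 ± 2.64 against 2.71 ± 1.2 CPM), si:ch211-196h16.5 (7.35 ± 0.740 against 0.465 ± 0.0803 CPM) and si:dkey-27b3.4 (5.06 ± 1.19 against 0.258 ± 0.112 CPM).

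At an unadjusted p under 0.05 there were 597 genes in neuroblastoma-like cells, where 602.1 are expected by chance, and DESeq2 called 32. The CPM of the genotypes did not overlap for 2213 genes (18.4%), where chance gives 20%. The edgeR count was 100 without MYCN tumor 1, 10 without MYCN tumor 2, 3 without MYCN;LMO1 tumor 2, and 0 without MYCN;LMO1 tumor 1 or tumor 3. On simulated counts with the same tumors, 24.4% of changes of 2 on the log2 scale and 75.5% of changes of 3 were recovered, and 0% of changes of 1. The class was spread over clusters unevenly between tumors: cluster 2 (crhbp, gch1 and hand2) held 68.0% of it in MYCN tumor 2, cluster 1 (tfap2b, phox2bb and slc6a2) 57.4% in MYCN;LMO1 tumor 1, cluster 0 (dbh and vgf) 59.4% in MYCN;LMO1 tumor 2, and cluster 8 (vipb and scg2b) 42.8% in MYCN;LMO1 tumor 3. In MYCN tumor 1, clusters 8 and 4 held 25.6% and 24.9%.

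**Figure D2:**
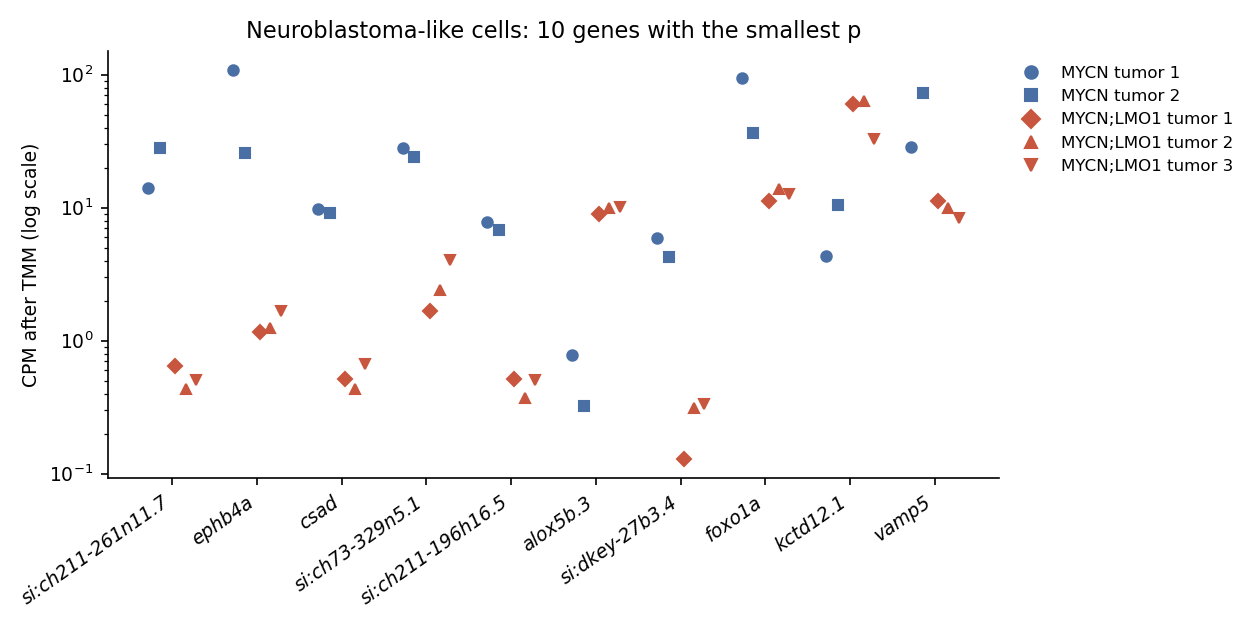
CPM after TMM scaling (log axis) in neuroblastoma-like cells for the 10 genes with the smallest p, with 1 point per tumor (blue, MYCN; red, MYCN;LMO1). For each gene the genotypes do not overlap, and si:ch211-261n11.7 alone passed the adjusted threshold (adjusted p = 0.0228).

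Of 17 gene lists fixed before the data were examined, 4 moved in neuroblastoma-like cells by camera with its preset correlation. Oxidative phosphorylation genes rose together by a median log2 fold change of 0.31, with 28 of 29 members positive (camera adjusted p = 1.00e-06). The call was lost with an estimated correlation (camera adjusted p = 0.200). That estimate was 0.0066, below the preset 0.01, so a stronger correlation among the genes did not end the call. No member passed over all genes tested or when adjusted over the list alone. The complex III gene uqcrb measured 11.9 ± 0.468 CPM in MYCN and 32.0 ± 7.10 CPM in MYCN;LMO1 tumors, the complex I gene ndufb10 50.7 ± 8.98 and 79.5 ± 4.25, the cytochrome oxidase gene cox6c 146 ± 10.6 and 215 ± 3.68, and the ATP synthase gene atp5po 235 ± 7.90 and 358 ± 63.7. The mean log2 CPM of the list was 6.26 and 6.29 in the MYCN tumors against 6.62, 6.68 and 6.61 in the MYCN;LMO1 tumors. The fry test, which asks whether the genes move on balance in 1 direction, gave an adjusted p of 0.0273. The other 3 lists called in these cells did not pass by fry. Their fry adjusted p was 0.737 (MHC class II presentation), 0.317 (chemokines and receptors) and 0.742 (interferon response). Neuroblastoma-like cells were deeper in the MYCN;LMO1 tumors (medians of 5095, 4936 and 4656.5 counts) than in the MYCN tumors (1991 and 3133 counts).

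The MHC class II presentation list fell by a median log2 fold change of -2.86, with 7 of 7 measured members lower (camera adjusted p = 6.61e-07, and adjusted p = 0.543 with an estimated correlation). The members were the invariant chain genes cd74a (505 ± 679 CPM in MYCN, 38.1 ± 26.1 in MYCN;LMO1) and cd74b (268 ± 361 and 19 ± 12.4), the class II chain gene mhc2dab (137 ± 186 and 6.47 ± 4.76), and the lysosomal processing genes ifi30, ctsh, ctss2.1 and ctss2.2. All 7 passed when adjusted over the list alone, and 0 passed over all genes tested. This difference was mainly that of MYCN tumor 2: cd74a measured 1090 CPM before TMM scaling there, against 33.5 CPM in MYCN tumor 1 and 41.1, 42.3 and 8.70 CPM in the MYCN;LMO1 tumors. Before scaling, MYCN tumor 1 also lay above each MYCN;LMO1 tumor for ctsh (17.3 against at most 8.17 CPM), ctss2.1 (13.1 against 4.82) and ctss2.2 (3.14 against 1.79). It did so barely for ifi30 (2.09 against 2.06), and not for cd74a, cd74b or mhc2dab. Without MYCN tumor 2 the median of the list was -0.03 and the call ended. Macrophage markers were present at low levels in the same cells, with c1qa at 5.21 CPM in MYCN tumor 2 against 0 to 0.370 CPM in the other tumors, and marco at 1.98 CPM against 2.61 CPM in MYCN tumor 1.

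**Figure D3:**
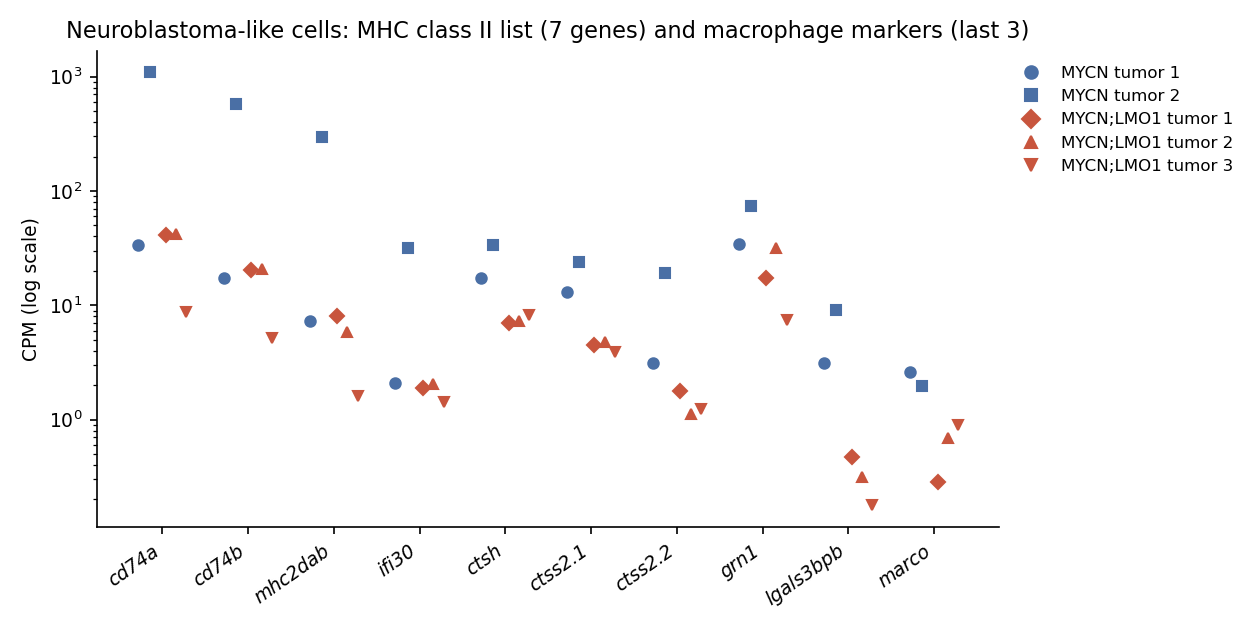
CPM (log axis) in neuroblastoma-like cells for the 7 measured MHC class II presentation genes and, at the right, the macrophage markers grn1, lgals3bpb and marco, with 1 point per tumor. MYCN tumor 2 stands at 1090 CPM for cd74a and the other tumors at 8.70 to 42.3 CPM.

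The chemokine list fell by a median log2 fold change of -1.21 in neuroblastoma-like cells, with 2 of 13 members positive (camera adjusted p = 7.79e-05, and adjusted p = 0.286 with an estimated correlation). The chemokine gene ccl35.1 measured 7.20 ± 4.06 CPM in MYCN and 1.19 ± 0.356 CPM in MYCN;LMO1 tumors and was the 1 member that passed when adjusted over the list alone. The Cxcl12 receptor genes cxcr4b (7.49 ± 5.03 and 2.45 ± 0.835 CPM) and cxcr4a (8.65 ± 5.00 and 2.95 ± 1.70 CPM) and the chemokine gene ccl34b.1 (2.41 ± 1.18 and 0.387 ± 0.404 CPM) did not. In neuroblastoma-like cells of the MYCN tumors, ccl35.1 stood at 0.178% and 0.293% of its macrophage-like CPM, and the macrophage marker c1qb at 0.123% and 0.406%. Members differed in this. In the same tumors cxcr4b stood at 1.19% and 0.421% of its macrophage-like CPM and the receptor gene ccr9a at 0.149% and 0.546%. Far higher were ccl19a.1, at 1659% and 315%, and cxcr4a, at 16.1% and 213%. Without MYCN tumor 2 the median of the chemokine list was -0.75 and its mean -0.42, still past the threshold. The interferon response list fell by a median of -0.48, with 3 of 17 members positive (camera adjusted p = 0.00497, and adjusted p = 0.543 with an estimated correlation). The guanylate-binding protein gene gbp1 measured 18.9 ± 2.86 and 8.42 ± 2.81 CPM, the antiviral gene mxc 5.70 ± 5.27 and 1.42 ± 0.656 CPM, and the transcription factor genes stat1b and irf1b 17.9 ± 9.17 and 8.45 ± 3.27, and 248 ± 101 and 110 ± 68.5 CPM. No member of the interferon list passed over all genes or when adjusted over the list alone. Without MYCN tumor 2 the interferon median was 0.20 and its direction turned. Its call also ended without MYCN;LMO1 tumor 3, at a median of -0.55, and with no low-count filter, at -0.37.

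The other 13 lists did not pass in neuroblastoma-like cells (camera adjusted p from 0.165 to 0.932), and 0 of their members passed over all genes or when adjusted over the list alone. The adrenergic core regulatory circuit, the transcription factors of the sympathetic tumor state, had a median log2 fold change of -0.61. In it hand2 measured 1157 ± 237 CPM in MYCN and 741 ± 292 CPM in MYCN;LMO1 tumors, phox2bb 394 ± 38.3 and 448 ± 272, tbx2b 15.1 ± 5.43 and 7.12 ± 2.89, and isl1 10.6 ± 5.50 and 40.1 ± 28.1. Catecholamine synthesis and storage had a median of -0.12, neuronal maturation 0.13 and the mesenchymal neuroblastoma state -0.30. In the mesenchymal list the Notch receptor gene notch2 measured 15.4 ± 10.5 and 3.07 ± 1.75 CPM. Extracellular matrix and integrins had a median of -0.21 and secreted proteases and matrix remodelling -0.52, in which the gelatinase gene mmp9 measured 17.5 ± 16.9 and 5.16 ± 0.572 CPM. The cell cycle list had a median of 0.48, dissociation stress 0.16, and glycolysis and hypoxia -0.03. In the stress list the heat shock gene hsp70.2 measured 33.2 ± 25.8 and 87.7 ± 37.1 CPM. Lists of mostly myeloid genes had medians of -0.27 (complement and phagocytosis), -0.22 (lipid handling and lysosome), -0.13 (macrophage alternative activation) and -0.41 (proinflammatory cytokines).

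For macrophage-like cells the question, given by the title of the series, was whether LMO1 in the tumor changes the macrophages around it. No gene of 5743 passed in edgeR (smallest adjusted p = 0.527), with 337 genes at an unadjusted p under 0.05 and 8 called by DESeq2. The 10 genes with the smallest p are therefore given as values. The chemokine gene ccl34a.4 measured 198 ± 30.5 CPM (SD, n = 2) in MYCN and 1259 ± 540 CPM (SD, n = 3) in MYCN;LMO1 tumors (log2 fold change 2.67, SE 0.51, edgeR adjusted p = 0.695). The activin receptor gene acvr1ba measured 3.26 ± 0.820 and 36.2 ± 7.63 CPM, and timm9, a mitochondrial import gene, 1.98 ± 0.990 and 26.6 ± 4.12 CPM. The locus si:ch211-261n11.7 measured 85.2 ± 8.32 CPM in MYCN and 0.995 ± 1.72 CPM in MYCN;LMO1 tumors, the latter from 5 counts in all. FP015862.2 measured 819 ± 227 and 155 ± 57.4 CPM, si:dkey-262k9.2 160 ± 112 and 27.2 ± 7.79 CPM, and si:dkey-260g12.1 20.2 ± 2.12 and 0.199 ± 0.345 CPM. Those with the higher values in MYCN;LMO1 tumors were si:dkey-25o1.7 (18.4 ± 4.3 and 158 ± 40.9 CPM), zgc:77112 (5.30 ± 3.87 and 75.0 ± 45.2 CPM) and si:ch211-9d9.1 (5.94 ± 2.97 and 132 ± 107 CPM).

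The CPM of the genotypes did not overlap for 1263 genes (22.0%) in macrophage-like cells, where chance gives 20%. Leaving out any tumor gave 0 calls. On simulated counts with these tumors, 29.2% of changes of 2 on the log2 scale, 79.6% of changes of 3 and 97.9% of changes of 4 were recovered. The class was also spread over clusters unevenly between tumors. Cluster 12 (lgals3bpb, plaua and c1qa) held 66.5% of it in MYCN tumor 2, cluster 15 (grn2, ctsd and gpnmb) 59.2% in MYCN;LMO1 tumor 1, cluster 11 (marco, c1qc and fgl2a) 47.9% in MYCN;LMO1 tumor 2, and clusters 10 and 11 41.3% each in MYCN;LMO1 tumor 3. Cluster 10 held 59.7% in MYCN tumor 1. Pooled over tumors, dbh, th, hand2 and phox2bb reached 35% of their neuroblastoma-like level in this cluster. In the whole macrophage-like class of MYCN tumor 1 they reached 3.11%, so the pooled value is not to be read for that tumor. The class held 77 and 478 cells in the MYCN tumors, and 287, 605 and 92 in the MYCN;LMO1 tumors.

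Camera called 7 of 17 lists in macrophage-like cells. Each of the 7 had an adjusted p of 0.564 with an estimated correlation and 0.684 by fry. The estimates ran from -0.022 (chemokines and receptors) to 0.789 (catecholamine synthesis and storage), against the preset 0.01. The number called was 11 without MYCN tumor 1, and 2 without MYCN;LMO1 tumor 1 or tumor 2. Oxidative phosphorylation genes rose by a median log2 fold change of 0.41, with 26 of 29 members positive (camera adjusted p = 1.30e-05). The cytochrome oxidase gene cox5ab measured 19 ± 0.309 CPM in MYCN and 45.0 ± 3.70 CPM in MYCN;LMO1 tumors, ndufb10 38.8 ± 13.3 and 86.3 ± 24.5, and uqcrb 19.7 ± 6.19 and 41.5 ± 6.99. Without MYCN tumor 2 the median was -0.06 and the call ended, and without MYCN tumor 1 it was 1.04. The interferon response list fell by a median of -0.47, with 2 of 13 members positive (camera adjusted p = 0.0186). In it stat1b measured 152 ± 30.9 and 40.6 ± 25.6 CPM, gbp1 237 ± 153 and 51.4 ± 39.4, mxc 450 ± 584 and 46.6 ± 18.4, and the interferon regulator irf7 245 ± 176 and 90.1 ± 12.9. Its call ended without MYCN tumor 1 (median -0.07) and without MYCN;LMO1 tumor 1 (median -0.29). Extracellular matrix and integrin genes rose by a median of 1.23 (camera adjusted p = 0.0186). Only 4 of the 31 genes on the list were measured, and all 4 were positive. They were the integrin genes itga5 (68.2 ± 47.6 and 171 ± 41.5 CPM) and itgb1a (22.9 ± 2.03 and 51.2 ± 30.5), the fibronectin gene fn1a (30.6 ± 28.8 and 97.3 ± 76.8) and tgfbi (47.4 ± 25.3 and 71.7 ± 54.3). All but itga5 overlapped between genotypes. That call ended without MYCN tumor 1 (median 1.71), MYCN tumor 2 (1.24) or MYCN;LMO1 tumor 2 (1.01). No member of these 3 lists passed over all genes or when adjusted over the list alone.

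Chemokine and receptor genes fell by a median of -1.07 in macrophage-like cells, with 2 of 17 members positive (camera adjusted p = 0.0482). When adjusted over the list alone, ccl34a.4 was higher in MYCN;LMO1 tumors, and 3 members were lower: the monocyte chemokine receptor gene ccr2 (49.3 ± 24.3 and 10.8 ± 4.0 CPM), ccl19a.1 (53.4 ± 56.6 and 9.14 ± 0.167) and ccl34b.1 (271 ± 337 and 23.1 ± 19.3). None of the 4 passed over all genes. The call ended without MYCN tumor 2 (median -0.51), MYCN;LMO1 tumor 1 (-0.72) or MYCN;LMO1 tumor 2 (-0.87).

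The other 3 called lists hold genes of the tumor cells. Catecholamine synthesis and storage rose by a median of 1.38 in macrophage-like cells (9 of 9 positive, camera adjusted p = 0.00905), neuronal maturation by 1.22 (10 of 10 positive, camera adjusted p = 0.00905) and the adrenergic core regulatory circuit by 1.30 (6 of 6 positive, camera adjusted p = 0.0186). As examples, dbh measured 41.7 ± 13.5 CPM in MYCN and 197 ± 222 CPM in MYCN;LMO1 tumors, phox2bb 15 ± 5.99 and 63.6 ± 30.4, the decarboxylase gene ddc 9.13 ± 1.55 and 41.1 ± 32.7, and the neuronal RNA-binding protein gene elavl3 18.7 ± 15.1 and 91.4 ± 65.7. In macrophage-like cells, dbh, th, hand2 and phox2bb together reached 3.11% and 5.61% of their neuroblastoma-like level in the MYCN tumors, and 18.8%, 27.7% and 4.24% in the MYCN;LMO1 tumors. Without cluster 10 the catecholamine median was 0.29 and the adrenergic median 0.70, and both calls ended. Neuronal maturation had too few measured genes there for a test, and only 1 of the 7 lists, oxidative phosphorylation, stayed past the threshold. The calls also ended without MYCN;LMO1 tumor 1 (medians 1.55, 1.44 and 0.29 in the order above) and without MYCN;LMO1 tumor 2 (0.80, 0.35 and 0.03), and those of the last 2 lists without MYCN tumor 2 (1.57 and 1.29).

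The 10 lists that were not called in macrophage-like cells (camera adjusted p from 0.0693 to 0.606) include those for polarization. Macrophage alternative activation had a median of 1.06 with 5 of 9 members positive. In it the arginase gene arg2 measured 31.5 ± 4.72 CPM in MYCN and 81.9 ± 42.4 CPM in MYCN;LMO1 tumors, and the mannose receptor gene mrc1b 276 ± 193 and 576 ± 227. Proinflammatory cytokines had a median of 0.18, and secreted proteases 0.74, where the metalloprotease gene adam8a measured 180 ± 78.9 and 480 ± 243 CPM and the urokinase gene plaua 641 ± 198 and 223 ± 141. Lipid handling and lysosome had a median of -0.06. Its member apoeb, the apolipoprotein E gene, measured 451 ± 475 and 17 ± 16.1 CPM and was the 1 lower gene when adjusted over the list alone. MHC class II presentation had a median of -0.47, with cd74a at 14128 ± 15098 and 6623 ± 3655 CPM. The medians were -0.12 for complement and phagocytosis (mean 0.02, so that median and mean differ in sign), -0.62 for the cell cycle, -0.26 for dissociation stress, 0.21 for glycolysis and hypoxia and 0.21 for the mesenchymal neuroblastoma state.

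Summed over all kept cells, which mixes expression with cell makeup, 8 of 13840 genes passed in edgeR and all 8 fell in MYCN;LMO1 tumors. They are named here after their values were seen, since none met the rule for named genes. The largest drops were in si:ch211-261n11.7 (34 ± 3.03 CPM in MYCN, 0.678 ± 0.142 in MYCN;LMO1; log2 fold change -5.59, SE 0.43, adjusted p = 0.00399) and ephb4a (39.9 ± 24.3 and 1.21 ± 0.372 CPM; -5.06, SE 0.52, adjusted p = 0.0158). The others were si:dkey-79f11.10 (-4.28), csad (-4.11), si:ch211-196h16.5 (-3.98), CABZ01073795.1 (-3.06), FP015862.2 (-3.05) and si:ch211-219a4.3 (-2.54), with adjusted p from 0.0158 to 0.0463. There were 1033 genes at an unadjusted p under 0.05 over all cells, where 692 are expected by chance, and DESeq2 called 140, of which 55 were higher and 85 lower. CPM did not overlap between genotypes for 3139 genes (22.7%), where chance gives 20%. The edgeR count over all cells was 89 without MYCN tumor 1 (27 higher, 62 lower), 42 without MYCN tumor 2 (6 higher, 36 lower), 3 without MYCN;LMO1 tumor 1 (apoa2 and apoa1b higher, si:ch211-261n11.7 lower) and 0 without MYCN;LMO1 tumor 3.

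Over all cells camera called 6 lists. Oxidative phosphorylation rose (median 0.35, adjusted p = 7.37e-06), as did neuronal maturation (0.38, adjusted p = 0.00180). MHC class II presentation fell (-1.48, adjusted p = 7.37e-06), as did chemokines and receptors (-1.12, adjusted p = 1.08e-05), interferon response (-0.66, adjusted p = 1.72e-05) and the cell cycle (-0.47, adjusted p = 0.00551). With an estimated correlation the adjusted p was 0.130 for the chemokine and interferon lists, 0.358 for oxidative phosphorylation and neuronal maturation, 0.408 for MHC class II and 0.494 for the cell cycle. The estimates for the chemokine and interferon lists were -0.040 and -0.034, below the preset 0.01. By fry the adjusted p was 0.0582 for the chemokine, interferon and oxidative phosphorylation lists, and 0.240 for MHC class II, neuronal maturation and the cell cycle. When adjusted over the list alone, 4 chemokine, 4 interferon and 2 MHC class II genes were lower and 1 chemokine gene higher. Adjusted in the same way, lists that were not called held 1 higher gene for complement, 1 higher for lipid handling and 1 lower for secreted proteases, and 0 list members passed over all genes. The MHC class II call ended without MYCN tumor 2 (median -0.12), the neuronal call without MYCN tumor 1 (0.60), and the cell cycle call without MYCN tumor 1 (-0.15) or MYCN;LMO1 tumor 2 (-0.21). The other 11 lists did not pass over all cells. Among these, median, mean and direction of test did not share a sign for complement and phagocytosis (median -0.51, mean 0.44, tested down), glycolysis and hypoxia (median -0.03, mean -0.16, tested up) and macrophage alternative activation (median 0.07, mean 0.05, tested down). The remaining medians were 0.26 for catecholamine synthesis, 0.22 for the mesenchymal state, 0.13 for proinflammatory cytokines, 0.12 for matrix and integrins, 0.09 for dissociation stress, 0.02 for the adrenergic circuit, -0.12 for secreted proteases and -0.34 for lipid handling and lysosome.

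T/NK-like and neutrophil-like cells were the only other classes with at least 20 cells in 2 or more tumors of each genotype. In T/NK-like cells 0 of 3543 genes passed in edgeR, with 74 at an unadjusted p under 0.05 and 2 called by DESeq2. In neutrophil-like cells 0 of 2527 genes passed in edgeR, with 95 at an unadjusted p under 0.05 and 1 called by DESeq2, CU499336.2 (182 ± 99.1 CPM in MYCN and 1525 ± 611 CPM in MYCN;LMO1 tumors; edgeR adjusted p = 0.0835), named after its value was seen. By chance 177.15 genes are expected under 0.05 in T/NK-like and 126.35 in neutrophil-like cells. The smallest sums per tumor were 93917 and 46065 counts, and MYCN tumor 2 held only 29 neutrophil-like cells. In neutrophil-like cells the edgeR count was 1 without MYCN tumor 1, 11 without MYCN tumor 2 and 8 without MYCN;LMO1 tumor 3. In T/NK-like cells, dbh, th, hand2 and phox2bb reached 11% and 14.6% of their neuroblastoma-like level in the MYCN tumors and 41.9%, 33.7% and 0.505% in the MYCN;LMO1 tumors. A test of whether the genotype difference was unlike in neuroblastoma-like and macrophage-like cells passed for 0 of 10452 genes in edgeR, with 470 at an unadjusted p under 0.05 and a smallest adjusted p of 0.466. DESeq2 was not run for that test.

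Proliferation was read as the share of neuroblastoma-like cells with at least 2 counts over the cell cycle list after thinning each cell to 500 counts. That share was 5.09% and 3.02% in the MYCN tumors and 0.959%, 1.23% and 1.86% in the MYCN;LMO1 tumors, means of 4.06% ± 1.46 (SD, n = 2) and 1.35% ± 0.463 (SD, n = 3). The difference of -2.71 percentage points had an exact permutation p = 0.2, the smallest possible. Neutrophil-like cells gave 3.75%, 6.90%, 2.91%, 4.69% and 3.49% in the same order of tumors, at median depths of 1233 to 3183 counts before thinning. All but the 5.09% of MYCN tumor 1 lay below the neutrophil-like share of their own tumor. Whether neutrophil-like cells divide was not tested, so they are no known baseline for cells that do not divide. With no such baseline and the smallest possible p at 0.2, these shares were not read as an order of the genotypes. Summed over its measured members, the cell cycle list gave 447 and 420 CPM in neuroblastoma-like cells of the MYCN tumors, and 391, 380 and 302 CPM in the MYCN;LMO1 tumors. Much of that sum was tubb2b, a tubulin gene, at 171 ± 68.9 CPM in MYCN and 94.9 ± 10.3 CPM in MYCN;LMO1 tumors, while 10 of the 15 members had positive log2 fold changes (median 0.48, list not called). Without thinning, the shares were 43.7% ± 2.69 in MYCN and 43.1% ± 4.22 in MYCN;LMO1 tumors.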

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

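The alternatives for other classes, the removal of top doublet scores, the 2 subsets of macrophage-like clusters, the cells of 1000 to 3000 counts and the unthinned cycling share were chosen after the results were seen. No class share passed under any alternative. In neuroblastoma-like cells the oxidative phosphorylation and chemokine calls at the preset correlation held under these alternatives and without any tumor, with chemokine means from -1.94 to -0.42. Both were lost with an estimated correlation (camera adjusted p = 0.200 and 0.286), where the estimates were 0.0066 and 0.044 against the preset 0.01. A stronger correlation thus does not explain the loss for oxidative phosphorylation. The estimated form also has fewer degrees of freedom, limited by the tumors and not the genes.

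Over all cells the number of genes was 95 with no low-count filter and 140 by DESeq2, against 8, and 0 (without MYCN;LMO1 tumor 3) to 89 (without MYCN tumor 1) with 1 tumor left out. In neuroblastoma-like cells it was 142 with no filter, 32 by DESeq2, 2 with RLE scaling, at 1000 counts and at Leiden resolutions 0.5 and 2.0 (ephb4a joined), and 0 among class-enriched genes or cells of 1000 to 3000 counts, where fewer genes were tested. It ran from 0 (without MYCN;LMO1 tumor 1 or 3) to 100 (without MYCN tumor 1). In macrophage-like cells it was 80 with no filter, 8 by DESeq2 and 0 otherwise. In other classes it was 9 with no filter, 3 by DESeq2, 8 at 1000 counts, and 0 (without MYCN;LMO1 tumor 1 or 2) to 11 (without MYCN tumor 2). Where a genotype was left with 1 MYCN tumor, that tumor was assumed to vary like the others. The cause was not tested for the other shifts.

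The number of lists called in macrophage-like cells, 7, was 2 at 1000 counts and at resolution 2.0, 3 with doublets kept, 4 at resolution 0.5 and with top doublet scores removed, and 1 without the cluster holding neuroblastoma RNA, with 2 (without MYCN;LMO1 tumor 1) to 11 (without MYCN tumor 1) when tumors were left out. The adrenergic list turned in tested direction at 1000 counts (mean 0.29) and without that cluster (mean 0.73), with means still positive, and the cause was not tested. The interferon list in neuroblastoma-like cells had means from -0.95 (without MYCN tumor 1) to 0.61 (without MYCN tumor 2), where it reversed. The cycling difference of -2.71 points was -0.54 at 3 or more counts, -7.11 thinned to 1000 counts and -0.63 unthinned, and these settings change the baseline by construction. Among single genes, lists and class shares, 532 values stayed on their side of the threshold, 49 gained it, 69 lost it and 3 reversed. A reversal was counted only where the main or the alternative value passed, so the 532 include changes of sign. The log2 fold change of the macrophage-like share ran from -1.03 to 0.88, and that of the neutrophil-like share from -1.95 to 1.81. With this depth and number of tumors, 0% of simulated changes of 1 on the log2 scale were recovered in neuroblastoma-like or macrophage-like cells.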

Other observations

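All values in this part were singled out after the results were seen, and the first paragraph is not tested. The T/NK-like class split into a cd8a and cd40lg cluster, an NK-like cluster (nkl.2, nkl.4 and prf1.7) and a small cluster with foxp3a, the regulatory T cell factor, with cd4-1 and cd28. The NK-like cluster made up 7.16% of kept cells in MYCN;LMO1 tumor 2 (362 of its 506 cells), against 2.08% and 2.53% in the MYCN tumors and 1.69% and 0.546% in the other MYCN;LMO1 tumors. The foxp3a cluster measured 1.11% and 1.05% in the MYCN tumors and 0.502%, 0.317% and 0.468% in the MYCN;LMO1 tumors, from 6 to 25 cells each. An unnamed cluster of 64 cells was led by the type 2 cytokine genes il13 and il4. Among macrophage-like cells, a cluster with fn1a and tnfa (48 cells) was found in MYCN;LMO1 tumor 2 only, and a cluster with cd74a and ccl35.1 held 33 cells, 30 of them from MYCN tumor 2.

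The 8 genes lower in MYCN;LMO1 tumors over all cells were followed into the class of highest CPM among 4, in tests written after the results were seen. The 4 were neuroblastoma-like, macrophage-like, T/NK-like and neutrophil-like cells. The median log2 fold change there was -3.38 (largest SE 1.19), so a different makeup of these classes alone does not account for the set. The gene si:dkey-79f11.10 was also among the leading genes of the hematopoietic progenitor-like cluster, which lay outside the 4. That cluster held 6.30% of MYCN tumor 1 and 0.396% to 1.48% of the other tumors, so the part of this gene's fall due to makeup was not settled. Single genes differed: CABZ01073795.1 was at -4.12 (SE 1.21) in neuroblastoma-like, -1.80 (SE 0.60) in macrophage-like and 0.09 (SE 1.03) in T/NK-like cells. In their class of highest CPM among the 4, si:dkey-79f11.10 (-1.21, SE 0.75) and si:ch211-219a4.3 (-0.75, SE 0.73) overlapped between genotypes. In neuroblastoma-like cells these 2 genes were at -3.94 (SE 1.03) and -3.19 (SE 0.74), with si:dkey-79f11.10 at -3.53 (SE 0.75) in macrophage-like cells. Free RNA was not tested for them. In the MYCN tumors si:ch211-261n11.7 was at least 2.53 times as high in macrophage-like as in neuroblastoma-like cells, against 0.0168 for dbh, so free RNA from tumor cells does not account for it. The locus was lower in every MYCN;LMO1 tumor in 4 of 4 classes, as a sequence variant carried by 1 line would give. This is no separate support for a variant, since the locus was picked for its fall over all cells. It held 5, 16 and 5 counts in the whole MYCN;LMO1 tumors, so low values in each class were nearly fixed in advance. An effect of LMO1 in all cells and the library part also coincide with genotype and were not separated.

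The MHC class II difference in neuroblastoma-like cells was weighed next, again with tests written after the results were seen. Without MYCN tumor 2 the median was -0.0301, which for the list as a whole fits a property of that tumor rather than of the genotype. In MYCN tumor 2 the 7 members stood at a median of 5.40% of their macrophage-like level, 4.73 times that of the highest of 8 macrophage markers (1.14%). RNA of the mean macrophage-like profile alone thus does not account for the list, though for ctss2.1 (0.762%) and ctss2.2 (1.08%) that stays open. The test cannot exclude RNA or doublets from cells rich in class II and poor in C1q. Cluster 26, with cd74a among its leading genes and a mean of 46.9 CPM for C1q genes and marco, had 30 of its 33 cells in MYCN tumor 2. Free RNA shared by every barcode of that tumor does not account for cd74a, found in 34.3% of thinned neuroblastoma-like cells (lower bound 31.9%) against an upper bound of 17.2% in neutrophil-like cells, from 1 of 29 cells. This rests on clusters 2 and 14, at 35.0% and 56.1%. The other neuroblastoma-like clusters with at least 20 cells there stood at 2.94% to 20.8%, with lower bounds under 17.2%, so for them free RNA stays open.

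For oxidative phosphorylation in neuroblastoma-like cells the deeper MYCN;LMO1 cells were weighed as a cause, with a test written after the result was seen. Among cells of 1000 to 3000 counts, with medians of 1617 to 1858 counts per tumor, the median log2 fold change was 0.34, against 0.31 over all neuroblastoma-like cells. The difference thus remained at like counts per cell. The window lay below the class medians of the MYCN;LMO1 tumors (4656.5 to 5095 counts) but held that of MYCN tumor 1 (1991). Clusters were not matched within it, so a difference in the kind or quality of cells was not excluded. The call was lost with an estimated correlation (adjusted p = 0.200), and library part coincides with genotype, so neither a batch difference nor an effect of LMO1 was separated.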
